A study of Mus musculus with 9 samples.

How the data were processed

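Total RNA of 9 samples was labelled with Cy5 and hybridised to one-colour arrays, per the labels' protocols, in 3 groups of 3: mock, imiquimod, and imiquimod with oral vanillin. The deposited table holds linear probe intensities for 26423 probes on 9 arrays. The submitters' processing notes name limma with no version, and the scanner, the background correction and any filter are not given in the sources used here. Sorted values of the 9 deposited columns differed by at most 2.45% among values above 100, medians differed by 0.00496 log2 units, and 1 to 3 values per array were at or below 0. Intensities equalised in this way cannot show a change of total signal between arrays.

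Values under 1 were set to 1, log2 was taken, and no further normalization or filter was applied, since the medians lay within 0.1 log2 units of each other. Each probe was fitted in limma 3.58.1 (R 4.3.3) with a coefficient per group over all 9 arrays and the default empirical Bayes step. Each comparison was adjusted by Benjamini-Hochberg over all probes, and a probe was called at an adjusted p under 0.05. The platform annotation gave 20377 probes with 1 gene symbol, 0 with several and 6046 with none. Through a reference table of the mouse assembly GRCm38.p6, used for names only, 18213 probes had a current symbol, 2126 an older synonym that was updated, and 38 kept the symbol as given, which made 17742 genes. A gene with several probes was represented by the probe with the highest mean over all arrays. The other probes entered an alternative and are named where they disagreed for a gene with a large change.

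The 33 gene lists and cell type marker lists were tested with camera (preset correlation 0.01, two-sided), adjusted over all lists in each comparison, and again with an estimated correlation and with fry. The genes named are the 8 largest rises and falls per comparison among called genes whose groups of 3 arrays did not overlap (chance gives 10% of genes without overlap), predicted genes passed over. A fixed set of cytokine and psoriasis genes (Il23a, Il12b, Il17a, Il17f, Il22, Il1b, Il6, Tnf, S100a8, S100a9, Krt16 and Defb4) and up to 4 members with the smallest p of each list described were added, and the largest changes of IMQ against mock were also given for vanillin against IMQ. Groups, lists, the test, the alternatives and this rule were chosen before the data were examined.

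The procedure was tested on simulated data made from the real means of the 26423 probes and their fitted spreads, shuffled between probes, with 50 probes changed at each size. Far fewer probes were thus changed than the 53.6%, 41.2% and 26.7% called in the data, so the recovery counts do not carry over to the data. Of the 50 changed by 1 log2 unit it recovered 37 for IMQ against mock, 40 for vanillin against IMQ and 41 for vanillin against mock. Unchanged probes called were 12, 11 and 4. At 0.5 log2 units it recovered 12, 8 and 5. Of 200 simulated lists without a change, 0 were called, but their genes varied independently, so lists of correlated genes were not tested. Alternatives changed the normalization, the filter on dim probes, the offset, the spread prior, the array weights, the arrays in the fit, the replicate number as a block, the threshold and the unit tested, and left out each array in turn. Chance values for comparisons that share arrays came from 20 simulations with group means from the data and noise from the fitted spread of each probe.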

Results

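RNA from the treated tissue of female BALB/c mice was measured on 9 one-colour arrays of 26423 probes, in 3 groups of 3 arrays. Mock mice received Vaseline cream on shaved back skin for 7 days. The group called IMQ here received imiquimod (an agonist of toll-like receptor 7 that is used to induce psoriasis-like skin inflammation in mice). The third group received imiquimod and 100 mg/kg of oral vanillin, the main aroma compound of vanilla. The tissue label names skin while the extraction text names muscle. On these arrays the cornified envelope list had a median intensity percentile of 98.6 and the skeletal muscle markers one of 98.0. Median intensities of the arrays ran from 629 to 631, and the number of arrays limits the precision of every value. Pearson correlations of log2 intensity across probes, which are not independent replicates, ran from 0.989 to 0.992 among mock arrays, 0.992 to 0.996 among IMQ arrays and 0.984 to 0.994 among vanillin arrays. Between groups they ran from 0.952 to 0.966 for mock against IMQ, 0.969 to 0.980 for mock against vanillin and 0.971 to 0.979 for IMQ against vanillin. The median SD of a probe was 0.158 log2 units in mock, 0.0792 in IMQ and 0.170 in vanillin skin. The labels do not state that the arrays came from separate mice, so the p-values measure only the spread between these arrays, which may be technical.

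**Figure D1:**
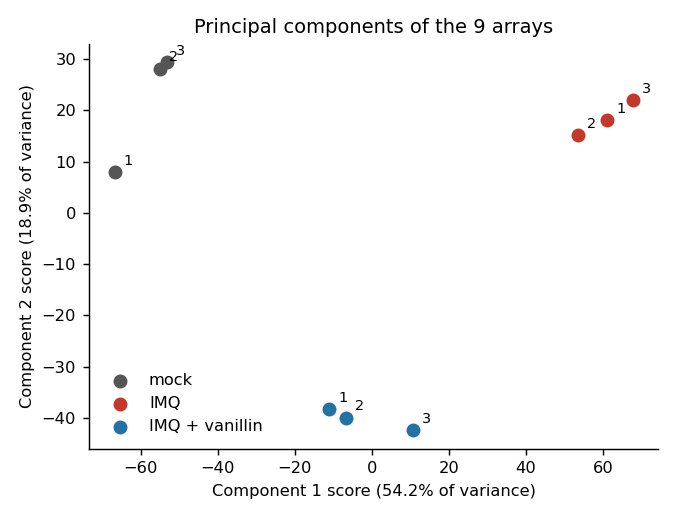
Scores of the 9 arrays on the principal components 1 and 2 of log2 intensity over all probes, with each point an array, coloured by group and numbered by replicate. Component 1 held 54.2% of the variance, with mock arrays between -66.7 and -53.2, vanillin arrays between -11.1 and 10.7 and IMQ arrays between 53.5 and 67.7. Component 2 held 18.9% and set the vanillin arrays, between -42.4 and -38.2, apart from both other groups. On it mock arrays lay between 7.9 and 29.3 and IMQ arrays between 15.2 and 21.9.

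The comparison of IMQ with mock asked what imiquimod changed in the skin. Among single genes the largest rises were those of Sprr2d and Krt6b. Sprr2d, a small proline-rich precursor of the cornified envelope, rose 228-fold, from a log2 intensity of 8.72 ± 0.08 to 16.55 ± 0.03 (SD, n = 3 arrays each), and Krt6b, a keratin of wounded and hyperproliferative epidermis, rose 198-fold. The log2 fold change was 6.63 ± 0.19 (SE, adjusted p = 1.18e-07) for Lce3f, a late cornified envelope protein, and 5.57 ± 0.15 (SE, adjusted p = 9.97e-08) for the serine protease inhibitor Serpinb12. For Il1f6, which encodes interleukin-36 alpha, it was 5.56 ± 0.08 (SE, adjusted p = 1.71e-09). It was 5.54 ± 0.09 (SE, adjusted p = 5.34e-09) for S100a9, a subunit of the antimicrobial protein calprotectin. The peroxidase Lpo rose by 5.31 ± 0.12 and the protease inhibitor Wfdc12 by 5.02 ± 0.10. The only probe of the serine protease Htra3 read 13.90 ± 0.23 (SD) in mock and 13.89 ± 0.14 in vanillin skin, but 2.80 to 3.42 on the IMQ arrays. That lies near the lowest intensities, so no fold is given, and a defect of this spot was not tested. Among other genes the largest fall was that of Ifitm6, of the interferon-induced transmembrane family, at -3.34 ± 0.20 (SE, adjusted p = 6.21e-06). Further falls were those of Nhs at -3.02 ± 0.14, the keratin Krt77 at -2.88 ± 0.09 and the ubiquitin ligase Trim2 at -2.87 ± 0.16. The secreted protein Crisp1 changed by -2.83 ± 0.13, the zinc finger gene Zfp62 by -2.60 ± 0.17 and Cd209a, a lectin of dendritic cells, by -2.55 ± 0.21.

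In the list of keratinocyte activation, 15 of 21 measured members were called higher, 4 lower and 2 were not called, and 19 were called when adjusted over the list alone (camera adjusted p = 2.49e-05, adjusted p = 0.0303 with an estimated correlation). Sprr2e rose by 4.63 ± 0.10 and Krt16, a partner of keratin 6, by 3.42 ± 0.09. For the cornified envelope and epidermal barrier the counts were 23 higher, 6 lower and 3 not called of 32, 30 called when adjusted over the list alone (camera adjusted p = 5.70e-07, adjusted p = 0.0216 with an estimated correlation), with Rptn (repetin) at 4.17 ± 0.11 and the epidermal protease Casp14 at 3.48 ± 0.08. The IL-1 and IL-36 family gave 10 higher, 1 lower and 2 not called of 13, 11 called when adjusted over the list alone (camera adjusted p = 6.20e-06, adjusted p = 0.0303 with an estimated correlation). Among its members Il1f9, which encodes interleukin-36 gamma, rose by 4.36 ± 0.10, the receptor antagonist Il1f5 by 3.22 ± 0.11, Il18 by 1.58 ± 0.08 and Il1b by 1.05 ± 0.11. Antimicrobial peptides and acute phase proteins also rose as a list, with 8 higher, 3 lower and 3 not called of 14, 11 called when adjusted over the list alone (camera adjusted p = 0.0200), a call lost at adjusted p = 0.0921 with an estimated correlation. Defb14 rose by 4.36 ± 0.12, the iron-binding lipocalin Lcn2 by 2.20 ± 0.10 and the protease inhibitor Slpi by 1.63 ± 0.10. S100a8, the partner of S100a9, read -0.06 ± 0.34 (SE, adjusted p = 0.897) on a dim probe (mean intensity at percentile 17.3), so a change could have been missed. Defb4 read -0.10 ± 0.09 (SE, adjusted p = 0.406).

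For the IL-23/IL-17 axis, 7 of 16 measured members were called higher, 1 lower and 8 were not called, and 8 were called when adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.0914 with an estimated correlation). Il23a, the p19 subunit of interleukin-23, rose by 1.94 ± 0.20 (SE, adjusted p = 8.29e-05), the chemokine Ccl20 by 1.36 ± 0.10, its receptor Ccr6 by 1.30 ± 0.10 and Il22ra2, a soluble receptor that binds interleukin-22, by 1.06 ± 0.08. Il12b, the p40 subunit shared with interleukin-12, was lower, at -0.88 ± 0.11 (SE, adjusted p = 0.000232). Neither Il17a (-0.09 ± 0.19, adjusted p = 0.698) nor Il17f (0.43 ± 0.20, adjusted p = 0.105) passed the test, nor did Il6 (-0.04 ± 0.21) or Tnf (0.24 ± 0.28), and no probe was named Il22. T cell and gamma delta T cell markers rose, with 9 higher, 2 lower and 3 not called of 14, 11 called when adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.0914 with an estimated correlation). The costimulator Icos rose by 1.88 ± 0.12, the regulatory T cell factor Foxp3 by 1.61 ± 0.17 and Cd8a by 1.70 ± 0.20. A dimmer probe of Cd8a read 0.50 (adjusted p = 0.0527) and was not called.

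Interferon response genes fell: 0 of 27 measured members were called higher, 22 lower and 5 were not called, and 22 were called when adjusted over the list alone (camera adjusted p = 6.20e-06, adjusted p = 0.0834 with an estimated correlation). The viral RNA sensor Ifih1 changed by -1.26 ± 0.09, the nucleic acid sensor Zbp1 by -1.55 ± 0.12, the guanylate-binding protein Gbp3 by -1.15 ± 0.09 and Isg15, a ubiquitin-like modifier, by -1.03 ± 0.08. Markers of several other cell types moved down beside this list. How much of each tissue the samples held was not measured, so it cannot be told apart from an effect of imiquimod on these genes. Adipocyte markers gave 0 higher, 11 lower and 4 not called of 15, 11 called when adjusted over the list alone (camera adjusted p = 0.000571, adjusted p = 0.0445 with an estimated correlation). The hormone adiponectin gene Adipoq read -1.55 ± 0.10. Melanocyte markers gave 0 higher, 7 lower and 0 not called of 7, 7 called when adjusted over the list alone (camera adjusted p = 0.000559, adjusted p = 0.0445 with an estimated correlation). The melanosome gene Oca2 read -2.42 ± 0.09. Schwann cell and nerve markers gave 0 higher, 6 lower and 0 not called of 6, 6 called when adjusted over the list alone (camera adjusted p = 0.00913, adjusted p = 0.236 with an estimated correlation). The myelin gene Pmp22 read -1.08 ± 0.07. Hair follicle keratins gave 1 higher, 16 lower and 7 not called of 24, 17 called when adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.0834 with an estimated correlation). The hair desmoglein Dsg4 read -2.38 ± 0.10. Skeletal muscle markers gave 1 higher, 8 lower and 4 not called of 13, 9 called when adjusted over the list alone (camera adjusted p = 0.0246, adjusted p = 0.0978 with an estimated correlation). The sarcomere gene Neb read -1.34 ± 0.11. Fibroblast markers gave 2 higher, 10 lower and 1 not called of 13, 12 called when adjusted over the list alone (camera adjusted p = 0.0493, adjusted p = 0.160 with an estimated correlation). Col3a1 read -1.46 ± 0.12 but Col1a1 read 2.24 ± 0.09. Of the 13 fibroblast markers 6 stand in another list, these collagen genes among them. The fibroblast call was lost in 5 of 9 fits with 1 array left out, namely IMQ replicates 1 and 2 and all vanillin replicates (adjusted p up to 0.0708 without IMQ replicate 2), and with the lowest 25% of probes left out (adjusted p = 0.0629) or the mean of a gene's probes taken (adjusted p = 0.0705).

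The other 20 of the 33 lists were not called for IMQ against mock. Those were other inflammatory cytokines, chemokines, toll-like receptor and NF-kB signalling, cell cycle, extracellular matrix, sterol and fatty acid synthesis, oxidative stress and housekeeping genes. The marker lists not called were those of sebaceous gland, neutrophil, monocyte and macrophage, dendritic cell, natural killer cell, B cell, mast cell, endothelium, basal keratinocyte, hair follicle stem cell, red blood cell and smooth muscle. For the natural killer, B cell and mast cell markers the median change was positive while the mean and the test pointed down. Of 26423 probes limma called 14157, 6330 higher and 7827 lower in IMQ. Among these 1864 rose and 1702 fell by at least 2-fold.

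**Figure D2:**
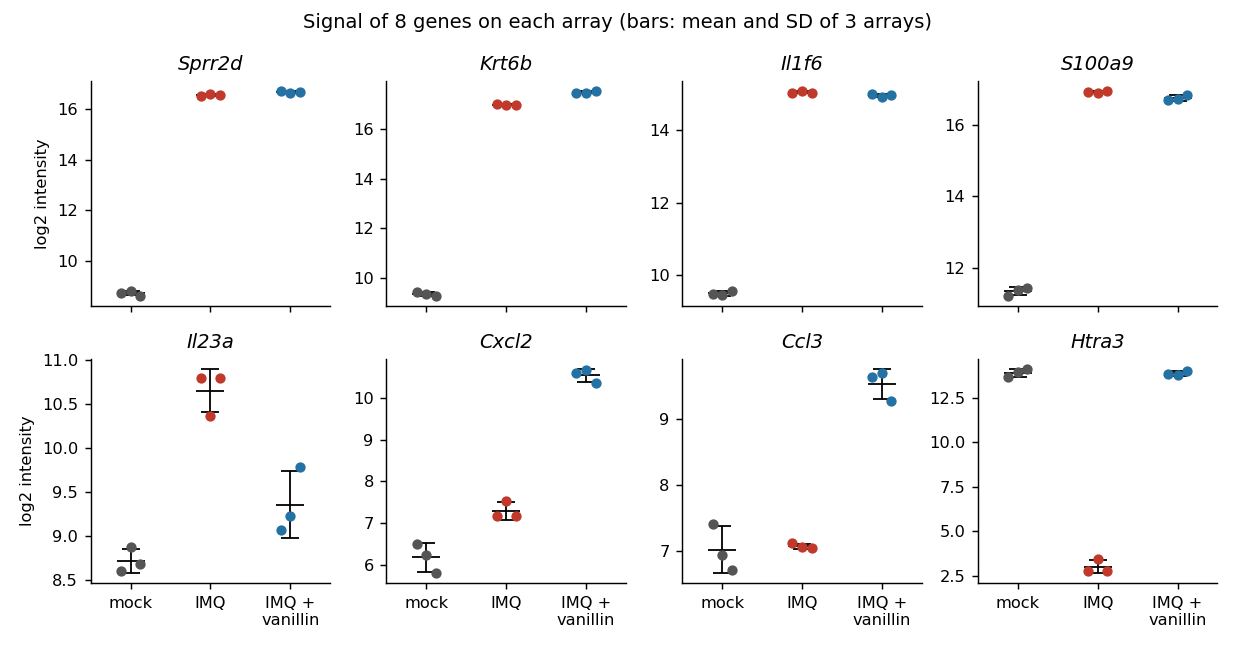
Log2 intensity of 8 genes on each of the 9 arrays by group, with points for arrays and bars for the mean and SD of 3 arrays. Sprr2d, Krt6b, Il1f6 and S100a9 lie high in both imiquimod groups, Il23a falls from 10.65 in IMQ to 9.35 in vanillin skin, Cxcl2 and Ccl3 rise with vanillin, and Htra3 is low on the IMQ arrays alone.

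The comparison of the vanillin group with IMQ asked what oral vanillin changed in imiquimod-treated skin, and the title of the series names the interleukin-23 and interleukin-17 axis. Il23a was lower with vanillin, at -1.30 ± 0.20 (SE, adjusted p = 0.00226), as were Ccl20 at -0.76 ± 0.10 and Il22ra2 at -0.42 ± 0.08, while Traf3ip2, the adaptor of the interleukin-17 receptor, was higher at 0.40 ± 0.08. Over that list the counts were 2 higher, 4 lower and 10 not called of 16, 6 called when adjusted over the list alone, and it was not called by camera (adjusted p = 0.200). Il17a (-0.35 ± 0.19, adjusted p = 0.171), Il17f (-0.02 ± 0.20), Il12b (0.08 ± 0.11) and Tnf (-0.59 ± 0.28) did not pass the test. Il1b rose by 0.59 ± 0.11 (SE, adjusted p = 0.00437) and Il6 by 1.01 ± 0.21 (SE, adjusted p = 0.00600), while Defb4 read -0.44 ± 0.09 and S100a8 -0.26 ± 0.34.

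Genes of chemokines, a matrix protease and a cytokine were among the largest rises with vanillin. Cxcl2, a neutrophil attractant, was 9.42-fold higher, at 3.24 ± 0.19 (SE, adjusted p = 0.000117), and Ccl3, which attracts monocytes, at 2.45 ± 0.18 (SE, adjusted p = 0.000286). Both were dim on the IMQ arrays, with Cxcl2 at 7.17 to 7.54 and Ccl3 at 7.05 to 7.12, beside a median log2 intensity of 9.30. The stromelysin Mmp10 was higher at 2.63 ± 0.17 (SE, adjusted p = 0.000166), Il24, a cytokine of the IL-10 family, at 2.04 ± 0.09 and Sprr2f at 2.13 ± 0.12. A probe annotated Mir137, not matched by its position, was also among the 8 largest rises. The only probe of Tent5d, a poly(A) polymerase gene, read 2.36 ± 2.05 (SD) in IMQ and 4.80 ± 0.28 in vanillin skin, among the lowest intensities, so no fold is given. Its call (adjusted p = 0.0417) was lost in 6 of 9 fits with 1 array left out, with array weights (adjusted p = 0.120) and with only both groups in the fit (0.0893). The Htra3 probe was called higher as well, against IMQ readings of 2.80 to 3.42 near the lowest intensities, and a defect of this spot was not tested. The chemokine list gave 9 higher, 3 lower and 10 not called of 22, 12 called when adjusted over the list alone, with Ccl4 at 1.66 ± 0.10 and Cxcl13 at 1.21 ± 0.10, but was not called by camera (adjusted p = 0.184). Neutrophil markers gave 10 higher, 1 lower and 7 not called of 18, 11 called when adjusted over the list alone (camera adjusted p = 0.117). The receptor Trem1 read 0.86 ± 0.08 and the growth factor receptor Csf3r read 1.25 ± 0.16.

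The 8 largest falls with vanillin were those of the olfactory receptor gene Olfr1499 (-3.12 ± 0.25), Brwd3 (-2.81 ± 0.20), the zinc finger gene Zfp423 (-2.79 ± 0.23) and Spef1 (-2.59 ± 0.23), followed by Clasrp (-2.55 ± 0.20), the phosphorylase kinase subunit Phka1 (-2.48 ± 0.38), the lipoprotein receptor Lsr (-2.46 ± 0.31) and the endocytosis gene Ehd1 (-2.40 ± 0.20). These 8 had IMQ against mock changes of 2.41 to 3.63, an opposite sign that their choice favours, since both comparisons share the IMQ arrays and no value without an effect was simulated for them. A dimmer probe of Lsr read -1.50 for IMQ against mock and 0.04 for vanillin against IMQ (adjusted p = 0.771), unlike the probe that named the gene.

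Of the genes that imiquimod had raised most, Sprr2d (0.11 ± 0.08, adjusted p = 0.292), Il1f6 (-0.08 ± 0.08), S100a9 (-0.16 ± 0.09), Lpo (-0.02 ± 0.12) and Wfdc12 (0.00 ± 0.10) did not pass the test for vanillin against IMQ. Krt6b rose by 0.50 ± 0.08 (SE, adjusted p = 0.00211), and Lce3f (-0.82 ± 0.19) and Serpinb12 (-0.82 ± 0.15) fell. Krt16 read 0.28 ± 0.09 (SE, adjusted p = 0.0416), a call lost in 7 of 9 fits with 1 array left out and with a replicate block (adjusted p = 0.0736). Of the genes imiquimod had lowered most, Ifitm6 rose by 1.02 ± 0.20, Nhs by 1.02 ± 0.14, Zfp62 by 1.34 ± 0.17 and Cd209a by 0.73 ± 0.21 (SE, adjusted p = 0.0239). Krt77 (-0.23 ± 0.09), Trim2 (0.12 ± 0.16) and Crisp1 (-0.33 ± 0.13) did not pass the test. The genes that imiquimod raised or lowered most were chosen on IMQ arrays that this comparison shares, which favours an opposite sign here. No value without an effect was simulated for them. The call for Cd209a was lost without vanillin replicate 1 (adjusted p = 0.0754) or 2, with array weights (0.0551) and with only both groups in the fit (0.0534), and its change was 0.46 without IMQ replicate 3. The keratinocyte activation list was not called (9 higher, 2 lower and 10 not called of 21, 11 called when adjusted over the list alone, camera adjusted p = 0.184). The cornified envelope list (7 higher, 4 lower and 21 not called of 32, 11 called when adjusted over the list alone, camera adjusted p = 0.677) was not called either. The IL-1 and IL-36 family gave 4 higher, 2 lower and 7 not called of 13, 6 called when adjusted over the list alone (camera adjusted p = 0.837).

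Camera called 2 of the 33 lists for vanillin against IMQ, both higher, and none of them with an estimated correlation. Both had been called lower for IMQ against mock, and sharing the IMQ arrays favours an opposite direction. Interferon response genes gave 16 higher, 1 lower and 10 not called of 27, 18 called when adjusted over the list alone (camera adjusted p = 0.00481, adjusted p = 0.316 with an estimated correlation). Ifi27l2a read 1.29 ± 0.12 and Ifih1 read 0.70 ± 0.09. Skeletal muscle markers gave 11 higher, 0 lower and 2 not called of 13, 11 called when adjusted over the list alone (camera adjusted p = 0.00417, adjusted p = 0.220 with an estimated correlation). Actn3, an actinin of fast fibres, read 0.86 ± 0.10 and Neb read 0.82 ± 0.11. How much muscle each sample held was not measured. A difference in that amount cannot be told apart from an effect of vanillin on these genes. Adipocyte markers, not called as a list, gave 10 higher, 1 lower and 4 not called of 15, 11 called when adjusted over the list alone (camera adjusted p = 0.0582). T cell markers, not called either, gave 4 higher, 7 lower and 3 not called of 14, 11 called when adjusted over the list alone (camera adjusted p = 0.267). For the antimicrobial list and the monocyte markers, neither called, the mean change was positive while the median and the test pointed down. Of all probes limma called 10898, 6412 higher and 4486 lower with vanillin. Among these 365 rose and 898 fell by at least 2-fold. Without IMQ replicate 1 the count was 6923 and without IMQ replicate 3 it was 6576.

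The changes with vanillin were compared with those with imiquimod over all probes. Of the 6330 probes that IMQ raised, 3337 were called lower with vanillin, 285 higher and 2708 neither. Against mock 2165 of them were still called higher. Of the 7827 probes that IMQ lowered, 4684 were called higher with vanillin, 157 lower and 2986 neither. Against mock 3207 of them were still called lower. Independent lists would have shared 1075 and 1899 probes in place of the 3337 and 4684 observed in these opposite directions. The vanillin change went the opposite way for 86.5% of the probes called for IMQ against mock. Both comparisons share the IMQ arrays, and 20 simulations with no vanillin effect gave 55.2% (range 54.5 to 55.6). The 3 shared arrays cannot be split so that each part keeps 2, and part of the excess may come from what they have in common. Across probes the 2 changes had a correlation of -0.713 beside -0.130 simulated, and a covariance of -0.278 beside -0.0193. With the call made without 1 IMQ array and the change measured against that array alone, the share was 84.6 to 86.7% over the 3 arrays. That argues against noise of single IMQ arrays as the source of the excess, but not against a signal common to all 3. Between both probes of the 1970 genes with exactly 2, the correlation of changes was 0.212 for IMQ against mock, 0.349 for vanillin against mock and 0.0363 for vanillin against IMQ. Among the 715 of these genes with both probes at or above the median signal the values were 0.337, 0.523 and 0.0181. For vanillin against IMQ the change of 1 probe was thus hardly related to that of the gene's other probe, and each change named above is the reading of 1 probe.

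Comparing the vanillin group with mock asked how far skin given both treatments still differed from mock skin. Krt6b was 281-fold higher, at 8.13 ± 0.08 (SE, adjusted p = 1.66e-10), and Sprr2d 246-fold higher, at 7.94 ± 0.08 (SE, adjusted p = 1.66e-10). The change was 5.81 ± 0.19 (SE, adjusted p = 2.62e-07) for Lce3f, 5.47 ± 0.08 for Il1f6, 5.39 ± 0.08 for Sprr2g, 5.37 ± 0.09 for S100a9, 5.29 ± 0.12 for Lpo and 5.14 ± 0.10 for Sprr2e. The only probe of the galectin gene Lgals2 read 4.65 ± 2.84 (SD) in mock and 0.43 ± 0.74 in vanillin skin, among the lowest intensities, so no fold is given. Its call (adjusted p = 0.0315) was lost without mock replicate 3, without vanillin replicates 1 and 2 (adjusted p up to 0.0856), with 16 added to each value (adjusted p = 0.120) and with only both groups in the fit (0.0644). Falls included Crisp1 (-3.16 ± 0.13), Krt77 (-3.11 ± 0.09) and the macrophage lectin Mgl2 (-2.97 ± 0.13). The same held for Trim2 (-2.75 ± 0.16), the membrane progestin receptor Paqr7 (-2.35 ± 0.07), Ifitm6 (-2.31 ± 0.20) and Serpinb6e (-2.25 ± 0.24). Il23a read 0.64 ± 0.20 (SE, adjusted p = 0.0421), a call lost in 7 of 9 fits with 1 array left out and with a replicate block (adjusted p = 0.0522), array weights (0.123) or only both groups in the fit (0.0717). Il1b rose by 1.64 ± 0.11, Il6 by 0.97 ± 0.21 and Krt16 by 3.70 ± 0.09, while Il12b (-0.80 ± 0.11) and Defb4 (-0.53 ± 0.09) fell. Il17a (-0.44 ± 0.19), Il17f (0.41 ± 0.20), Tnf (-0.35 ± 0.28) and S100a8 (-0.31 ± 0.34) did not pass the test.

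Of the 33 lists, 19 were called for vanillin against mock, 13 higher and 6 lower, and 10 of them held with an estimated correlation. The keratinocyte activation list was higher, with 13 higher, 2 lower and 6 not called of 21, 16 called when adjusted over the list alone (camera adjusted p = 2.92e-09). So was the cornified envelope list, with 23 higher, 3 lower and 6 not called of 32, 29 called when adjusted over the list alone (camera adjusted p = 1.73e-11). The IL-1 and IL-36 family gave 11 higher, 0 lower and 2 not called of 13, 11 called when adjusted over the list alone (camera adjusted p = 2.92e-09). These 3 held with an estimated correlation. Toll-like receptor and NF-kB genes gave 13 higher, 1 lower and 12 not called of 26, 15 called when adjusted over the list alone (camera adjusted p = 8.40e-05, adjusted p = 0.0159 with an estimated correlation). The NF-kB cofactor Bcl3 read 1.62 ± 0.10 and the prostaglandin synthase Ptgs2 read 1.33 ± 0.12. Neutrophil markers gave 9 higher, 2 lower and 7 not called of 18, 11 called when adjusted over the list alone (camera adjusted p = 0.000318, adjusted p = 0.0237 with an estimated correlation). The chemokine receptor Cxcr2 read 2.68 ± 0.14. T cell markers were higher, with 5 higher, 0 lower and 9 not called of 14, 5 called when adjusted over the list alone (camera adjusted p = 0.00335, adjusted p = 0.0476 with an estimated correlation). Antimicrobial peptides gave 7 higher, 2 lower and 5 not called of 14, 9 called when adjusted over the list alone (camera adjusted p = 0.00375, adjusted p = 0.0476 with an estimated correlation). Monocyte and macrophage markers gave 7 higher, 1 lower and 7 not called of 15, 8 called when adjusted over the list alone (camera adjusted p = 0.00385, adjusted p = 0.179 with an estimated correlation). The macrophage receptor Adgre1 read 1.92 ± 0.09. The chemokine list gave 9 higher, 5 lower and 8 not called of 22, 16 called when adjusted over the list alone (camera adjusted p = 0.0331, adjusted p = 0.111 with an estimated correlation). Cxcl2 read 4.35 ± 0.19, from a dim log2 intensity of 5.81 to 6.51 on the mock arrays, and Cxcl12, a homeostatic chemokine, read -1.55 ± 0.08. Other inflammatory cytokines gave 6 higher, 1 lower and 13 not called of 20, 10 called when adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.0796 with an estimated correlation). Il24 read 2.66 ± 0.09 and Il19 read 1.71 ± 0.21. The IL-23/IL-17 axis was called higher, with 6 higher, 1 lower and 9 not called of 16, 7 called when adjusted over the list alone (camera adjusted p = 0.0460, adjusted p = 0.129 with an estimated correlation). That call was lost without mock replicate 1 and without vanillin replicates 1 and 3 (adjusted p up to 0.150), and the chemokine call was lost without mock replicate 1 (adjusted p = 0.0708). A replicate block also ended the call of the IL-23/IL-17 axis (adjusted p = 0.0570), as did the mean of a gene's probes (adjusted p = 0.0532). With the lowest 25% of probes left out the axis had adjusted p = 0.0651, the chemokines 0.0532 and the other cytokines 0.0882.

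Interferon response genes were lower than in mock, with 1 higher, 13 lower and 13 not called of 27, 16 called when adjusted over the list alone (camera adjusted p = 0.000107, adjusted p = 0.0861 with an estimated correlation), and the protease Usp18 read -1.36 ± 0.15. Hair follicle keratins gave 0 higher, 15 lower and 9 not called of 24, 15 called when adjusted over the list alone (camera adjusted p = 1.25e-06, adjusted p = 0.00929 with an estimated correlation). Melanocyte markers gave 0 higher, 6 lower and 1 not called of 7, 7 called when adjusted over the list alone (camera adjusted p = 5.09e-06, adjusted p = 0.0148 with an estimated correlation). Adipocyte markers were lower, with 0 higher, 7 lower and 8 not called of 15, 12 called when adjusted over the list alone (camera adjusted p = 0.000318, adjusted p = 0.0237 with an estimated correlation). Schwann cell markers gave 0 higher, 4 lower and 2 not called of 6, 4 called when adjusted over the list alone (camera adjusted p = 0.00335, adjusted p = 0.197 with an estimated correlation). Hair follicle stem and sheath cell markers gave 0 higher, 6 lower and 5 not called of 11, 8 called when adjusted over the list alone (camera adjusted p = 0.00869, adjusted p = 0.0679 with an estimated correlation). Skeletal muscle markers were not called (3 higher, 2 lower and 8 not called of 13, 6 called when adjusted over the list alone, camera adjusted p = 0.809). Sterol and fatty acid synthesis genes were higher, with 10 higher, 4 lower and 9 not called of 23, 15 called when adjusted over the list alone (camera adjusted p = 0.0460, adjusted p = 0.197 with an estimated correlation). Oxidative stress genes were higher as well, with 8 higher, 3 lower and 11 not called of 22, 12 called when adjusted over the list alone (camera adjusted p = 0.0365, adjusted p = 0.186 with an estimated correlation). The sterol call was lost without mock replicates 1 and 2, IMQ replicate 2 and vanillin replicates 1 and 2 (adjusted p up to 0.0838), and the oxidative stress call without vanillin replicate 2 (adjusted p = 0.0672). With the lowest 25% of probes left out the sterol list had adjusted p = 0.0651 and the oxidative stress list 0.0532, and a replicate block gave the sterol list adjusted p = 0.0691. Among lists not called, the median and the mean differed in sign for extracellular matrix, skeletal muscle, mast cell and smooth muscle. The number of probes called was 7045, 3152 higher and 3893 lower. Among these 579 rose and 606 fell by at least 2-fold. The spread used here also came from the IMQ arrays, whose median SD (0.0792) was below that of mock (0.158) and vanillin skin (0.170). Pooling them may make these p-values too small. With only both groups in the fit, which also leaves fewer arrays, 4727 probes were called. Both comparisons against mock called 2165 probes higher and 3207 lower, where independent lists would share 755 and 1153. The change went the same way for 84.1% of the probes called for IMQ against mock, beside 55.0% simulated without a treatment effect in the vanillin group. The covariance of these changes was 0.260 beside 0.0187 simulated, and part of the excess may come from the 3 shared mock arrays.

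**Figure D3:**
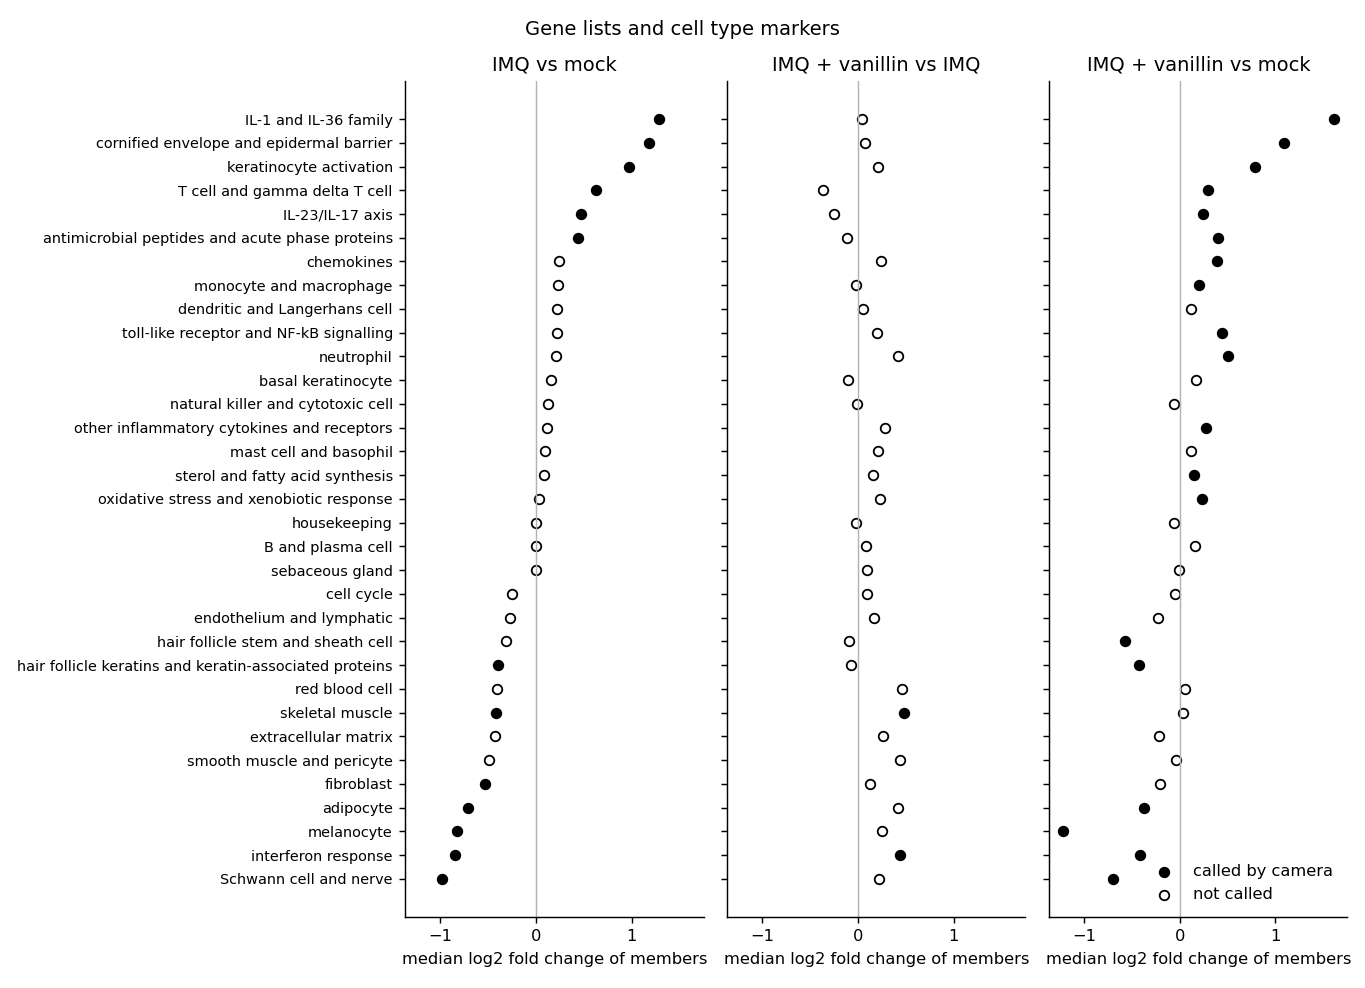
Median log2 fold change of the members of 33 gene lists and marker lists in the 3 comparisons, with filled points for lists called by camera with the preset correlation and open points for the others. The IL-1 and IL-36 family lies at 1.28 for IMQ against mock and 1.61 for vanillin against mock, and the interferon list at -0.84 and -0.42.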

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

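Leaving out the dimmest 50% of probes tested fewer probes and called 8594 for IMQ against mock and 6935 for vanillin against IMQ. Requiring a log2 change of at least 1 lowered the counts to 3566, 1263 and, for vanillin against mock, 1185, or without adjustment to 3615, 1327 and 1214, by construction. With 1 array left out the counts ran from 11551 to 15901, 6576 to 12805 and 5507 to 7767, and vanillin against IMQ fell to 6923 without IMQ replicate 1 and to 6576 without IMQ replicate 3; the cause was not tested. With the replicate number as a replicate block they were 13609, 9968 and 6224, although 2 of 9 pairs of same-numbered arrays had a residual correlation over 0.1. Scaling by quantiles, medians or 75th percentiles, the offset and the spread prior moved no count by over 1.5 times. The deposited columns were already equalised, so the scalings could hardly move a count. Array weights gave 19830, 16208 and 10260 probes. With only both groups in the fit the counts were 15635, 11338 and 4727. An estimated correlation left 5, 0 and 10 lists called in place of 13, 2 and 19, and fry, which asks another question, called 30, 24 and 25. The opposite sign share of 86.5% was 84.6% without the dimmest 25% of probes, 77.2% over the 500 probes with the smallest p, 84.6% against IMQ array 2 alone and 82.7 to 88.1% with 1 array left out, the lowest without mock replicate 1. It was 90% over genes whose probes all changed one way with IMQ, an alternative chosen after seeing the data (82.6% of 144 raised and 93.5% of 306 lowered genes). Of 8695 alternatives for named genes 2 turned the sign where the main fit or the alternative called the gene, and other changes of sign were not counted. Both came with the mean of a gene's probes: Jchain, vanillin against IMQ, at -0.0904 and Pnpla2, vanillin against mock, at 0.00797. The 2 probes of Jchain, both dim (mean intensity at percentiles 21.2 and 8.6), were called in opposite directions. They read 0.78 and -0.96 for vanillin against IMQ, and -1.44 and 0.80 for IMQ against mock. Many alternatives could not turn a sign, since they leave the fold change as it is. These were the spread prior, the replicate block, only both groups in the fit and a left-out array of the third group. Of 1485 alternatives for lists 0 turned the direction of a call. Each alternative listed in advance was run.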

Other observations

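The tests of other probes, of the brightest probes, of neutrophil markers and of random lists beside the interferon list were chosen only after those results were seen. Extracellular matrix genes gave 6 higher, 15 lower and 7 not called of 28, 21 called when adjusted over the list alone for IMQ against mock (camera adjusted p = 0.0861). The adhesive glycoprotein genes Fn1 (-1.53 ± 0.13) and Tnc (-1.37 ± 0.09) fell, as did Sparc (-1.09 ± 0.09), while Col1a1 rose by 2.24 ± 0.09. Of the 28 genes 7 stand in another list, such as Col1a1 among the fibroblast markers, so both lists partly report the same readings. With vanillin against IMQ the list gave 13 higher, 2 lower and 13 not called of 28, 15 called when adjusted over the list alone (camera adjusted p = 0.0895). The matrix metalloproteinase genes Mmp13 (1.37 ± 0.14) and Mmp9 (0.75 ± 0.10) rose beside Mmp10. Cell cycle genes gave 6 higher, 15 lower and 11 not called of 32, 22 called when adjusted over the list alone for IMQ against mock (camera adjusted p = 0.297), with cyclin E1 gene Ccne1 higher by 1.37 ± 0.09 and cyclin B2 gene Ccnb2 at -0.99 ± 0.13. Vanillin against IMQ gave 13 higher, 4 lower and 15 not called of 32, 17 called when adjusted over the list alone (camera adjusted p = 0.630).

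Sebaceous gland markers gave 4 higher, 5 lower and 4 not called of 13, 9 called when adjusted over the list alone for IMQ against mock (camera adjusted p = 0.785), and the wax ester synthase gene Awat2 fell by 1.28. Mast cell markers gave 2 higher, 4 lower and 5 not called of 11, 6 called when adjusted over the list alone (camera adjusted p = 0.829). The mast cell receptor Mrgprb2 read -1.83 ± 0.11 and the basophil protease Mcpt8 0.91 ± 0.07. Dendritic and Langerhans cell markers gave 6 higher, 3 lower and 7 not called of 16, 9 called when adjusted over the list alone (camera adjusted p = 0.259), with the costimulator Cd86 higher by 0.90 ± 0.09. In vanillin against IMQ the invariant chain gene Cd74 fell by 1.04 and the maturation marker Cd83 rose by 0.77 ± 0.09. Basal keratinocyte markers gave 4 higher, 4 lower and 2 not called of 10, 8 called when adjusted over the list alone (camera adjusted p = 0.584), with the integrin gene Itga6 higher by 0.77 ± 0.12.

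Probes that imiquimod moved one way and vanillin the other were checked against other probes of the same genes. The changes of a gene's other probes were averaged, and each share counts the checked probes by the sign of that mean. Of 586 raised probes that returned, 49.5% had other probes higher with IMQ (95% exact interval 45.4 to 53.6, beside 42.8% over all). For 46.2% the other probes were lower with vanillin (42.2 to 50.4, beside 44.8%). The median changes of the other probes were -0.00317 and 0.04, beside 0.88 and -0.68 for the probes themselves, so single probes may be a source of the fall. For the rise this stays open as well. Other probes at or above the median signal gave 49.8% (44.0 to 55.6), an interval that holds the 44.2% over all such probes. For raised probes that did not return, the same share was 67.4% (61.6 to 72.8). The median change of those other probes was 0.30, beside -0.00081 for raised probes that returned. Raised probes that returned were thus backed less by other probes of their genes. Of the 144 genes whose probes were all called raised, however, 82.6% went the opposite way. No value without a vanillin effect was simulated for that share. Among 994 lowered probes that returned, 67.1% had other probes lower with IMQ (64.1 to 70.0, beside 57.2%). For 61.1% the other probes were higher with vanillin (58.0 to 64.1, beside 55.2%). The median changes of the other probes were -0.25 and 0.12, beside -0.76 and 0.59 for the probes themselves. The intervals here take probes as independent, although probes of the same gene count for each other on the same arrays, so they are too narrow. The share lower with IMQ lay clearly above that over all, which argues against single probes as the whole cause of the fall with IMQ. Both checks share the IMQ arrays that chose the probes. Of 666 lowered probes that did not return, 66.2% had other probes lower with IMQ. For 55.3% of these 666 the other probes were higher with vanillin (51.4 to 59.1). Whether single probes are the whole cause of the rise with vanillin is not decided. The intervals of 61.1% and 55.3%, already too narrow, overlap. Dim probes alone are argued against as well, since 75.5% of raised and 78.7% of lowered probes among the brightest 25% went the opposite way, above every simulation without a vanillin effect. An effect of vanillin on these genes stays open, as does an unequal hybridisation of the IMQ arrays, which the design does not separate from the treatment.

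Some chemokine genes, Cxcl2 and Ccl3 among them, were higher with vanillin than with imiquimod alone (9 of 22 measured, with 3 lower and 10 not called), and camera did not call the list (adjusted p = 0.184, adjusted p = 0.316 with an estimated correlation). A response of the tissue at collection could raise immediate early genes, whose median change lay at percentile 36.9 of 10000 random lists of like signal (camera adjusted p = 0.969). Of 19 such genes 4 were called higher and 5 lower, so the median decides nothing: Fos rose by 1.74, Dusp1 by 0.92, Nr4a1 by 0.90 and Klf6 by 0.45, while Egr3, Ier2, Nr4a2, Klf4 and Ier3 read -0.43 to -0.30, all named after their values were seen, and this explanation stays open. More neutrophils could bring some of these transcripts: the median of neutrophil markers lay at percentile 99.5 of random lists, but camera did not call the list (adjusted p = 0.117), so this cannot be told apart from chemokines made by resident cells. Of the 18 markers 7 stand in another list, 10 were called higher, such as Retnlg (1.20 ± 0.12), Mmp9 (0.75 ± 0.10) and Camp (0.42 ± 0.08), and 1 lower, while Ltf (-0.13 ± 0.19) and S100a9 (-0.16 ± 0.09), which was already high with IMQ, did not pass the test; these 5 were named after their values were seen.

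Interferon response genes were lower with imiquimod, a toll-like receptor 7 agonist. A general fall of genes at their signal level is argued against: 0 of 10000 random lists of like signal had a median as low as -0.84 (95% of them lay between -0.39 and 0.24). The call did not hold with an estimated correlation (adjusted p = 0.0834 with an estimated correlation), and whether the time of collection or a change in cell types plays a part was not tested.

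The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With only both groups in the fit, the real split called 15635 probes for IMQ against mock, 11338 for vanillin against IMQ and 4727 for vanillin against mock. Each time 1 of the 10 splits, the real one, called as many. The highest of the other splits called 0, 0 and 1. Those splits mix both groups on each side, so the group difference adds to the spread and few calls follow whatever its cause. The low counts therefore say nothing about that cause.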
